A study of Mus musculus with 35 samples.

How the data were processed

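The series holds 35 Affymetrix arrays of mouse lung, 1 per animal and each labelled a biological replicate, in 5 groups of 5, 5, 5, 10 and 10. The lungs were lavaged before removal and frozen, RNA was taken with Trizol and a column clean-up, and it was labelled with the Affymetrix whole-transcript kit, per the labels' protocols. The values are deposited log2 signals from RMA, and the submitters' processing notes also name Affymetrix Expression Console and Partek, without a version or the role of each. The labels give no batch, run date or pairing of animals.

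The deposited table held 35557 probe sets: 21789 carried 1 gene symbol in the gene table supplied with it, 1621 carried several and 12147 were not in that table. For each gene the probe set with the highest mean over the 35 arrays was kept among those with 1 symbol, which left 19938 genes, 999 of them with more than 1 probe set. No filter on level was applied.

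Group means were fitted over all 35 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and 6 contrasts were taken: ventilation at low stretch against none, hypercapnia at low and at high stretch, high against low stretch in normocapnia and in hypercapnia, and the interaction of CO2 and stretch. All tests were two-sided. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, adjusted within the contrast. Errors are limma standard errors for changes and SD over arrays for group means. Groups, contrasts, tests and most alternatives were fixed before the data were examined.

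The lists, 42 with 711 of 772 genes measured, were also fixed before the data were examined, while the lists described in the report were chosen after their results were seen. Each was tested with camera at its preset correlation of 0.01, with an estimated correlation between genes, and with fry, adjusted over the 42 lists. The preset correlation gave many calls without an effect: on simulated data with no list shifted it called on average 12.5 lists for ventilation, 13.3 for hypercapnia at low stretch, 7.9 for high stretch in normocapnia, 11.5 for hypercapnia at high stretch, 12 for high stretch in hypercapnia and 12.3 for the interaction. It was kept because it had been fixed in advance, and the p with an estimated correlation stands beside each call.

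Named genes follow 1 rule. In each comparison these are the 10 largest rises and 10 largest falls among genes that passed (5 and 5 for high stretch in hypercapnia), or the 5 genes with the smallest p where none passed, with 2 to 4 of the largest members of each list described. Ttpa, Adam17 and Alox5 are named throughout because the laboratory had studied them, and Ttpa had been chosen on these arrays. Predicted genes and clones, small RNAs, ribosomal RNAs, olfactory and vomeronasal receptors and immunoglobulin and T cell receptor segments were left out of the largest changes only.

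The share of stretch genes that moved the opposite way with CO2 used random splits of the 10 high stretch normocapnia arrays into 5 and 5, 1 part in each contrast, over 100 splits. The correlation of CO2 effects at both stretch levels used genes called in either with the real labels. Both were compared with 100 permutations of the CO2 labels. The counts of calls were compared with 100 splits of the arrays, the real one included.

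The procedure was tested on simulated data over 19938 genes. Changes of 0.3, 0.6 and 1 log2 were recovered in 34.6, 90.2 and 99.2% for ventilation, 37.6, 89 and 98.8% for hypercapnia at low stretch, 45.5, 95.1 and 99.2% for high stretch in normocapnia, 67.2, 97.3 and 99.7% for hypercapnia at high stretch, 47, 94.8 and 99.1% for high stretch in hypercapnia, and 20, 79.6 and 95.5% for the interaction. Of the called genes 6.55, 6.47, 1.93, 1.86, 1.46 and 1.78% were unchanged ones, in the same order. With a simulated stretch effect and no CO2 effect the opposed share was 49.8 ± 4.62% with the split and 53.4 ± 4.33% without (SD, 20 simulations). The simulated changes had random signs in randomly drawn genes, so this SD is not the chance range of the observed share. On the real arrays the permuted shares ran from 12.7 to 85.5% with the split. Without it they ran from 21.8 to 91%, with a median of 59.8%.

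Alternatives were fits of only the compared groups, the replicate number as a block, array weights, and eBayes with its trend and robust options. Others were genes above the median level, all probe sets or their mean per gene, arrays centred on their median, a second quantile normalization, and fits without 1 array. The opposed share was also taken without the split and for stretch changes of at least 1 log2 unit. The array spread as a covariate, and fits without the lowest-spread array of each group, were added after the data had been seen.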

Results

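RNA of mouse lung, lavaged before removal, was measured on 1 Affymetrix array per animal. The animals were 35 adult male C57BL/6J mice, an inbred laboratory strain. The question set by the title of the series is how hypercapnia, a raised level of CO2, alters lung injury caused by mechanical ventilation. Spontaneously breathing mice formed the non-ventilated group (5 arrays). Low stretch ventilation ran for 3 h at a tidal volume of 10 mL/kg, a positive end-expiratory pressure of 2 cmH2O and 135 breaths per minute, either in room air (low stretch normocapnia, 5 arrays) or with 12% CO2 in room air (low stretch hypercapnia, 5 arrays). High stretch ventilation ran for 3 h at 35 to 40 mL/kg, a peak inspiratory pressure of 27 cmH2O, an end-expiratory pressure of 0 cmH2O and 30 to 35 breaths per minute in 75% oxygen, without CO2 (high stretch normocapnia, 10 arrays) or with 12% CO2 (high stretch hypercapnia, 10 arrays). Each comparison of high with low stretch is therefore a comparison of tidal volume, end-expiratory pressure, breathing rate and oxygen together. The values were log2 signals whose array medians lay between 6.96 and 7.05. The SD over all probe sets of an array averaged 2.22 ± 0.03 (SD, n = 5) in the non-ventilated group, 2.22 ± 0.01 (n = 5) and 2.22 ± 0.02 (n = 5) in the low stretch groups without and with CO2. It was 2.24 ± 0.02 (n = 10) in each high stretch group. The number of arrays limits the precision, and no array file was a copy of another.

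Ventilation at low stretch was compared with spontaneous breathing to show what 3 h of ventilation and its preparation did without a large tidal volume. Neutrophil genes dominated the rises. Mmp8, the neutrophil collagenase, went from 6.86 ± 1.04 to 11.07 ± 0.38 (log2 signal, SD, n = 5 each), an 18.5-fold rise with an adjusted p of 7.64e-11. Il1r2, the decoy receptor of interleukin-1, rose 16.7-fold, Retnlg 11.3-fold, the calcium-binding protein gene S100a8 10.7-fold and the chemokine receptor gene Cxcr2 8.87-fold. The myeloid lectin receptor genes Clec4e (10.4-fold) and Clec4d (9.42-fold), the cystine transporter gene Slc7a11 (9.38-fold), the acute phase gene Saa3 (9.14-fold) and Slfn4 (8.81-fold) completed the 10 largest rises. In each of these 10 genes all 5 ventilated arrays lay above every non-ventilated array. The largest falls were smaller than the largest rises and included B cell and vascular genes. Ms4a1, which encodes the B cell antigen CD20, fell 2.73-fold (log2 change -1.45 ± 0.16, SE, adjusted p 5.03e-08), and Aplnr, the apelin receptor of endothelial cells, fell 2.79-fold.

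Of the 22 measured neutrophil markers 17 rose, 1 fell and 4 did not pass (18 and 1 adjusted over the list alone), with a median log2 change of 2.09. The list was called by camera with an adjusted p of 1.03e-23 (adjusted p = 0.0191 with an estimated correlation). The 15 measured B cell markers all fell, over all genes and adjusted over the list alone (camera adjusted p 5.16e-26, and adjusted p = 0.00318 with an estimated correlation). Among them were Fcer2a (2.67-fold), the B cell receptor component Cd79a (2.57-fold), Bank1 (2.52-fold) and Ms4a1. Cr2, a complement receptor of B cells, fell 2.46-fold. Of 23 endothelial markers 14 fell and 9 did not pass (16 fell adjusted over the list alone), with a median of -0.28 (camera adjusted p 6.4e-12, and adjusted p = 0.0191 with an estimated correlation). Sox17 fell by 0.78, Egfl7 by 0.72 and the VEGF receptor gene Kdr by 0.71 on the log2 scale. Other vascular genes among the largest falls were Edn1, which encodes endothelin 1 (2.52-fold), Tmem100 (2.35-fold) and the connexin gene Gja5 (2.28-fold), beside the transcription cofactor gene Lbh (2.5-fold). Alveolar type 2 markers moved less: 3 of 14 fell and 11 did not pass (4 fell adjusted over the list alone), with a median of -0.09 (camera adjusted p 0.0034, and adjusted p = 0.3 with an estimated correlation). Lpcat1 fell by 0.47 and Etv5 by 0.41. T cell markers fell for 5 of 17 genes while 12 did not pass (7 fell adjusted over the list alone), with a camera adjusted p of 0.000117 and an adjusted p = 0.306 with an estimated correlation. Cd2 fell by 0.74 and Ccr7 by 0.59.

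Stress hormone and antioxidant genes rose with ventilation. Glucocorticoid receptor targets rose for 19 of 21 genes, also adjusted over the list alone, with none lower and 2 not passing (median 0.65, camera adjusted p 5.16e-26, and adjusted p = 0.00193 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 5.5-fold from 9.13 ± 0.72 to 11.59 ± 0.12 (SD, n = 5 each). The pyruvate dehydrogenase kinase gene Pdk4 rose 3.65-fold, and the metallothionein genes Mt2 and Mt1 rose 3.77-fold and 2.73-fold. Both metallothionein genes are also in the list of NRF2, metallothionein and antioxidant genes. Of that list 12 of 22 rose, 1 fell and 9 did not pass (12 and 1 adjusted over the list alone), with a camera adjusted p of 1.62e-12 and an adjusted p = 0.00541 with an estimated correlation. Hmox1, the heme-degrading enzyme, rose 3.18-fold and the sulfiredoxin gene Srxn1 2.87-fold. Interleukin-6 and STAT3 targets rose for 13 of 19 genes, also adjusted over the list alone, with 6 not passing (camera adjusted p 5.05e-11, but adjusted p = 0.0968 with an estimated correlation). The feedback inhibitor gene Socs3 rose 2.7-fold, Lrg1 1.96-fold and Il4ra 1.93-fold. Of 16 p53 targets 6 rose, 1 fell and 9 did not pass (7 and 2 adjusted over the list alone; camera adjusted p 0.0012, and adjusted p = 0.0191 with an estimated correlation). Gadd45a rose by 1.03 and Trp53inp1 by 0.89. The unfolded protein and ATF4 list had 8 of 24 genes higher and 16 not passing (9 higher adjusted over the list alone), with a camera adjusted p of 0.000156 and an adjusted p = 0.161 with an estimated correlation. It was led by Slc7a11. Sesn2 rose by 0.73, Ddit4 by 0.72 and the serine synthesis gene Psat1 by 0.63.

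Monocyte and interstitial macrophage markers rose for 4 of 17 genes with 13 not passing (7 higher and 1 lower adjusted over the list alone), among them Vcan 4.33-fold and F13a1 3.14-fold. The camera call of that list (adjusted p 0.0177, but adjusted p = 0.306 with an estimated correlation) was lost without non-ventilated replicate 4 (adjusted p 0.0769). Platelet markers rose for 3 of 11 genes with 8 not passing (5 higher adjusted over the list alone; camera adjusted p 0.00103, but adjusted p = 0.313 with an estimated correlation). The platelet tubulin gene Tubb1 was at 0.68 with an adjusted p of 0.0199, which became 0.0622 without non-ventilated replicate 5 (0.58) and 0.101 without low stretch normocapnia replicate 4 (0.48). The platelet chemokine gene Ppbp was at 0.54 with an adjusted p of 0.12. None of the 20 interferon response genes passed, over all genes or adjusted over the list alone. Rsad2 was at 1.07 (adjusted p 0.0616) and Mx2 at 0.77 (adjusted p 0.283). The camera call of the interferon list (adjusted p 0.00641, but adjusted p = 0.6 with an estimated correlation) was lost without low stretch normocapnia replicate 1 (adjusted p 0.354). Among genes above the median level the interferon response and the monocyte and interstitial macrophage markers also lost their call (adjusted p 0.115 and 0.0544). Ttpa, which encodes the alpha-tocopherol transfer protein, rose by 0.60 ± 0.16 (SE, adjusted p 0.00777), whereas the sheddase gene Adam17 (0.04, adjusted p 0.806) and the 5-lipoxygenase gene Alox5 (0.30, adjusted p 0.0599) did not pass.

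In all, limma called 2353 of 19938 genes for ventilation, 1322 higher and 1031 lower, of which 133 were higher and 20 lower by at least 1 log2 unit. Camera with its preset correlation called 26 of 42 lists, and 6 with an estimated correlation. Random regroupings of the arrays also gave many camera calls with the preset correlation, so each list is described here by its genes and by both p-values. With only the 10 arrays of both groups in the fit the gene count was 1385.

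**Figure D1:**
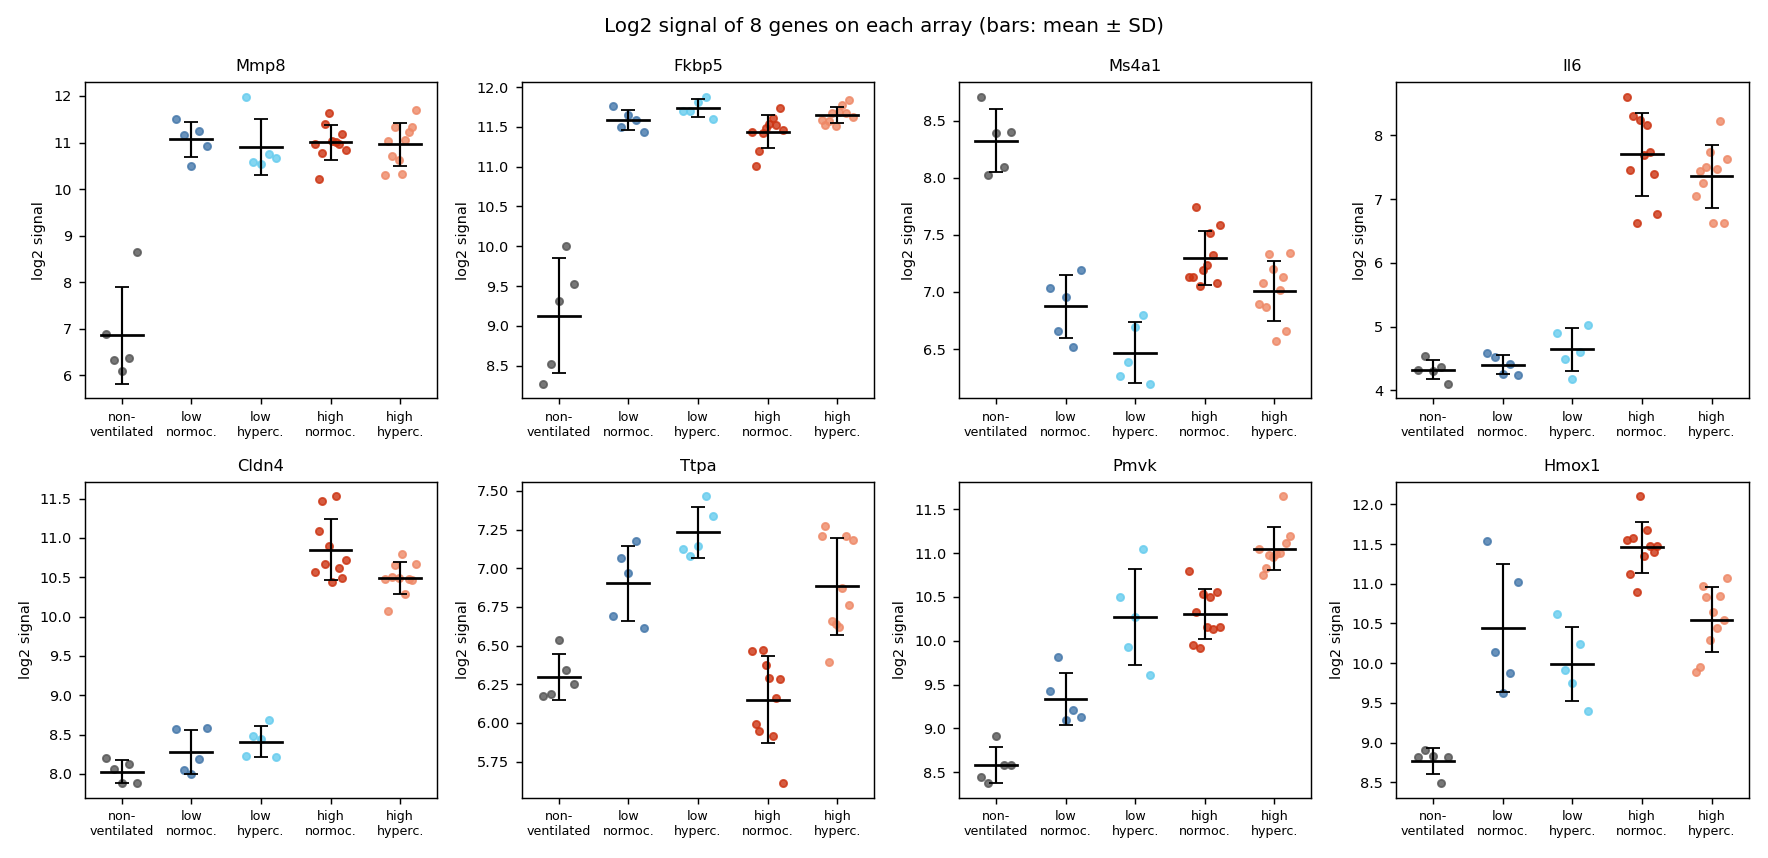
Log2 signal of 8 genes on each of the 35 arrays, 1 point per array, by group (normoc., normocapnia; hyperc., hypercapnia), with the group mean and SD as bars; each vertical axis covers its own gene's range and does not start at 0. Mmp8 averaged 6.86 without ventilation and 11.07 at low stretch normocapnia, Il6 averaged 4.40 at low and 7.70 at high stretch normocapnia, and Hmox1 averaged 11.46 at high stretch normocapnia and 10.55 at high stretch hypercapnia.

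Hypercapnia at low stretch was compared with low stretch normocapnia to show the effect of inspired CO2 without a large tidal volume. Few genes passed. Pmvk, which encodes phosphomevalonate kinase of the cholesterol pathway, rose 1.91-fold from 9.33 ± 0.29 to 10.27 ± 0.55 (SD, n = 5 each, adjusted p 0.0308), and Ramp3, an accessory protein of the calcitonin receptor family, rose 1.65-fold. The other rises were in Ccr8 (1.55-fold), Tubb2b (1.37-fold), the ETS repressor gene Erf (1.35-fold, adjusted p 0.00364), Capn5 (1.34-fold), Fbxo44 (1.28-fold) and Zbtb7b (1.23-fold). The largest falls were in Ints7, a subunit of the Integrator complex (1.36-fold, adjusted p 0.00128), and in Zfp518a (1.36-fold). Others were in the mitochondrial RNA-binding gene Fastkd2 (1.34-fold), the NAD synthesis gene Nmnat1 (1.33-fold), the mTOR subunit gene Mlst8 (1.31-fold), Ankrd37 (1.31-fold), Ino80c (1.3-fold), the Fanconi anaemia gene Fancl (1.29-fold), Ubxn8 (1.24-fold) and the sodium-proton exchanger gene Slc9a8 (1.23-fold). In Pmvk 4 of the 5 hypercapnia arrays lay above every normocapnia array. In each of the other named genes that passed all 5 lay beyond every normocapnia array. Ttpa (0.33 ± 0.16, SE, adjusted p 0.521), Adam17 (-0.13, adjusted p 0.59) and Alox5 (-0.05, adjusted p 0.942) did not pass.

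Cholesterol synthesis had 1 of 18 genes higher and 17 not passing (2 higher adjusted over the list alone). Pmvk was followed by Mvd at 0.30 (adjusted p 0.111) and Sqle at 0.26 (adjusted p 0.331). The median of the list was 0.12, with a camera adjusted p of 0.000166, but adjusted p = 0.992 with an estimated correlation. No neutrophil marker of 22 passed, over all genes or adjusted over the list alone, the median being -0.23. Ly6g was at -0.76 (adjusted p 0.612) and Wfdc21 at -0.53 (adjusted p 0.348). The camera call of the neutrophil list (adjusted p 0.0179, but adjusted p = 0.992 with an estimated correlation) was lost without low stretch normocapnia replicate 1 (0.21) or 2 (0.0651) or low stretch hypercapnia replicate 2 (0.105), 3 (0.129) or 5 (0.0845), the values being adjusted p. Limma called 23 genes, 8 higher and 15 lower, none by 1 log2 unit or more. An unadjusted p under 0.05 was found for 1839 genes against 997 expected by chance. The count was 4, 6 and 3 without low stretch normocapnia replicate 3, 4 or 5, and 7, 4, 5 and 14 without low stretch hypercapnia replicate 1, 3, 4 or 5. Of the 18 named genes that passed, 2 (Erf and Ints7) kept their call in every fit that left out 1 array. The count was 0 with only these 10 arrays in the fit, 4 with all probe sets, 64 after a second quantile normalization, 78 among genes above the median level and 100 with the array spread as a covariate. Camera called 5 lists, and 0 with an estimated correlation (11 had an unadjusted p under 0.05 with the preset correlation, and fry called 0).

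High stretch was compared with low stretch in normocapnia to show the response to injurious ventilation settings. Il6, the inflammatory cytokine, rose 9.8-fold from 4.40 ± 0.15 (SD, n = 5) to 7.70 ± 0.66 (SD, n = 10, adjusted p 5.67e-12). Cldn4, a tight junction claudin, rose 5.94-fold (log2 change 2.57 ± 0.14, SE, adjusted p 5.78e-15), Sfn, which encodes the epithelial 14-3-3 sigma protein, 5.1-fold, and Ptgs2, the inducible cyclooxygenase, 4.42-fold. The immediate-early transcription factor genes Egr2 (4.88-fold), Fosb (4.41-fold), Atf3 (4.26-fold) and Egr1 (3.71-fold), the TWEAK receptor gene Tnfrsf12a (3.39-fold) and the cholesterol hydroxylase gene Ch25h (3.29-fold) were the rest of the 10 largest rises. In 9 of the 10 genes all 10 high stretch arrays lay above every low stretch array (8 of 10 in Atf3). Falls were smaller: Fam216b fell 2.24-fold, the cholecystokinin receptor gene Cckar 2.07-fold, Slc10a5 2-fold, Fam13a 1.98-fold and Ankub1 1.94-fold. Tat, the tyrosine aminotransferase, fell 1.92-fold, Acss3 1.85-fold, Kcnrg 1.84-fold, Frem1 1.82-fold and Olfml1 1.81-fold.

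Immediate-early transcription factors and phosphatases rose for 23 of 27 genes, also adjusted over the list alone, with 4 not passing (median 0.72, camera adjusted p 7.98e-29, and adjusted p = 0.00552 with an estimated correlation). Of the stretch-responsive YAP, SRF and TGF-beta targets 11 of 22 rose and 11 did not pass (14 higher and 2 lower adjusted over the list alone), with an adjusted p of 2.45e-09 and an adjusted p = 0.00552 with an estimated correlation. The matricellular genes Ccn1 and Thbs1 rose 3.13-fold and 3-fold, the tissue factor gene F3 2.86-fold and Ccn2 1.75-fold. ADAM17 and EGF receptor ligands, a list of that protease, the receptor, its ligands and their regulators, rose for 11 of 22 genes, fell for 1 and did not pass for 10 (13 and 1 adjusted over the list alone; camera adjusted p 1.14e-07, and adjusted p = 0.0111 with an estimated correlation). The ligand genes Hbegf and Ereg rose 2.79-fold and 2.27-fold, the feedback inhibitor gene Spry4 1.99-fold and the ATP receptor gene P2ry2 1.95-fold. Adam17 itself was at -0.02 ± 0.06 (SE, adjusted p 0.908). Matrix metalloproteinases and their inhibitors rose for 9 of 21 genes, with 1 lower and 11 not passing (10 and 1 adjusted over the list alone; camera adjusted p 1.83e-05, and adjusted p = 0.0402 with an estimated correlation). The hyaluronan synthase gene Has1 rose 2.98-fold, the aggrecanase gene Adamts4 2.81-fold, Timp1 2.43-fold and Mmp19 2.26-fold. Coagulation and fibrinolysis genes rose for 9 of 18, fell for 1 and did not pass for 8 (10 and 2 adjusted over the list alone; camera adjusted p 1.26e-05, but adjusted p = 0.0543 with an estimated correlation). Plaur, the urokinase receptor, rose 2.65-fold and Plau 1.76-fold beside Thbs1 and F3.

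Inflammatory cytokines and chemokines rose for 11 of 24 genes with 13 not passing (13 higher adjusted over the list alone; median 0.61, camera adjusted p 1.12e-11, but adjusted p = 0.051 with an estimated correlation), led by Il6 and Ptgs2. The chemokine genes Ccl3 and Ccl2 rose 3.13-fold and 2.58-fold. NF-kappaB feedback and adhesion targets rose for 13 of 20, fell for 1 and did not pass for 6, also adjusted over the list alone (camera adjusted p 1.22e-08, but adjusted p = 0.244 with an estimated correlation). Ier3 rose 2.22-fold, Bcl3 2.07-fold, Tnip3 1.79-fold and the endothelial selectin gene Sele 1.74-fold. Of 17 junction genes 7 rose, 4 fell and 6 did not pass, also adjusted over the list alone (camera adjusted p 0.00261, but adjusted p = 0.271 with an estimated correlation). The claudin genes Cldn4, Cldn7 (1.63-fold) and Cldn3 (1.41-fold) rose with the occludin gene Ocln (1.47-fold). The NRF2, metallothionein and antioxidant list had 11 of 22 higher, 2 lower and 9 not passing (13 and 2 adjusted over the list alone; camera adjusted p 0.000174, but adjusted p = 0.2 with an estimated correlation). Slc7a11 rose 2.55-fold, Srxn1 2.24-fold, Hmox1 2.03-fold and Mt2 1.85-fold. Hypoxia-inducible and glycolytic genes rose for 9 of 25, fell for 3 and did not pass for 13 (10 and 3 adjusted over the list alone; camera adjusted p 0.0101, but adjusted p = 0.227 with an estimated correlation). Bhlhe40 rose 2.36-fold, the adrenomedullin gene Adm 2.04-fold, the glucose transporter gene Slc2a1 1.62-fold and the hexokinase gene Hk2 1.54-fold. In the unfolded protein and ATF4 list 9 of 24 rose, 3 fell and 12 did not pass (10 and 3 adjusted over the list alone; camera adjusted p 0.00646, but adjusted p = 0.311 with an estimated correlation). The amino acid synthesis genes Psat1 and Asns rose 1.74-fold and 1.55-fold, and Ddit4, which encodes an mTOR inhibitor, fell 1.48-fold.

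B cell markers were higher at high than at low stretch for 8 of 15 genes, with 7 not passing (10 higher adjusted over the list alone; median 0.28, camera adjusted p 2.96e-05, but adjusted p = 0.271 with an estimated correlation). The same 5 low stretch normocapnia arrays served in the ventilation contrast, so chance low values in that group would give a fall there and a rise here. A recovery of B cell markers cannot be read from these contrasts. In hypercapnia, on other ventilated arrays, the list mean was 6.86 ± 0.14 (SD, n = 5) at low and 7.17 ± 0.14 (n = 10) at high stretch. It was 7.91 ± 0.21 (n = 5) without ventilation. These values argue against chance low values in the low stretch normocapnia group as the only source. Fcer2a was at 0.58 and Bank1 at 0.55, calls that were lost without low stretch normocapnia replicate 1 for Fcer2a (0.41, adjusted p 0.077) and replicate 4 for Bank1 (0.46, adjusted p 0.0524). Among genes above the median level the B cell markers lost their call (adjusted p 0.18), as did the hypoxia-inducible and glycolytic genes (adjusted p 0.054) and the unfolded protein and ATF4 response (adjusted p 0.103). Neutrophil markers did not differ by any test in the lavaged lungs. None of 22 passed, over all genes or adjusted over the list alone, with a median of 0.04 (camera adjusted p 0.71). Cells washed out by the lavage were not measured, so a difference in the airspaces cannot be read from these arrays. Club, goblet and ciliated cell markers fell for 4 of 19 genes, also adjusted over the list alone, with 15 not passing. The dynein gene Dnah5 fell by 0.34 and the ciliated cell gene Cdhr3 by 0.30, and the dynein gene Dynlrb2 was at -0.32, a call that did not hold in every setting. The camera call of that list (adjusted p 0.0136, but adjusted p = 0.573 with an estimated correlation) was lost without low stretch normocapnia replicate 1 (adjusted p 0.0757). Ttpa fell by 0.75 ± 0.14 (SE, adjusted p 0.000108), with all 10 high stretch arrays below every low stretch array. Alox5 did not pass (0.17, adjusted p 0.216). Limma called 3646 genes, 1739 higher and 1907 lower (83 and 2 by at least 1 log2 unit), and camera called 17 lists, 4 of them with an estimated correlation.

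**Figure D2:**
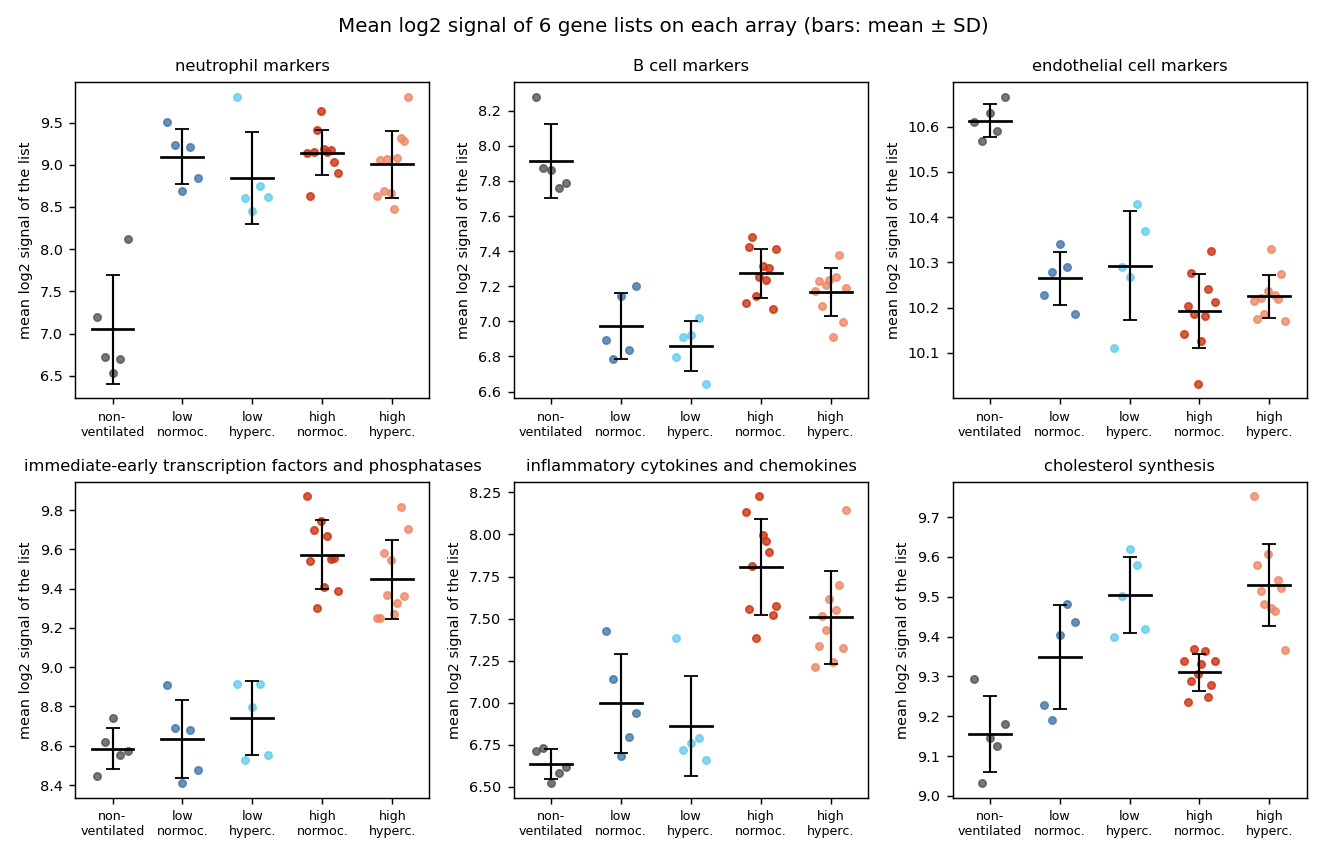
Mean log2 signal of the measured members of 6 gene lists on each of the 35 arrays, 1 point per array, by group (normoc., normocapnia; hyperc., hypercapnia), with the group mean and SD as bars; each vertical axis covers its own list's range and does not start at 0. B cell markers averaged 7.91 without ventilation, 6.97 at low stretch normocapnia and 7.27 at high stretch normocapnia, and cholesterol synthesis genes averaged 9.31 at high stretch normocapnia and 9.53 at high stretch hypercapnia.

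Hypercapnia at high stretch was compared with high stretch normocapnia, the comparison closest to the title of the series. Pmvk rose 1.68-fold from 10.30 ± 0.29 to 11.05 ± 0.24 (SD, n = 10 each, adjusted p 0.000577). Ttpa rose 1.66-fold from 6.15 ± 0.28 to 6.88 ± 0.31 (n = 10 each, adjusted p 8.29e-05), with 9 of 10 hypercapnia arrays above every normocapnia array. This gene was singled out by the laboratory on these arrays, so its rise is not independent evidence. Further rises were in P2ry10 (1.59-fold), the retinol dehydrogenase gene Rdh12 (1.58-fold), the mast cell protease gene Prss34 (1.46-fold), Cckar (1.44-fold), Plcxd3 (1.42-fold), the amino acid transporter gene Slc38a4 (1.41-fold), the carbonic anhydrase gene Car14 (1.4-fold) and Stat4 (1.38-fold). Hmox1 fell 1.89-fold (log2 change -0.92 ± 0.19, SE, adjusted p 0.00233), and the chemokine genes Cxcl5 and Ccl2 fell 1.86-fold and 1.77-fold. The other large falls were in the transcription factor gene Spic (1.82-fold), the natural killer receptor gene Ncr1 (1.66-fold), Timp1 (1.66-fold), the anion exchanger gene Slc26a4 (1.64-fold), Ccn2 (1.63-fold), Rnd1 (1.58-fold) and Sh2d4a (1.55-fold, adjusted p 3.9e-06, all 10 hypercapnia arrays below every normocapnia array). Adam17 (-0.10, adjusted p 0.274) and Alox5 (-0.14, adjusted p 0.332) did not pass.

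Cholesterol synthesis genes rose for 8 of 18 with 10 not passing (14 higher adjusted over the list alone). They were led by Pmvk, the lanosterol synthase gene Lss (1.33-fold, adjusted p 4.21e-05), Msmo1 (1.24-fold) and the squalene synthase gene Fdft1 (1.24-fold). The cholesterol list had a camera adjusted p of 7.46e-13 but an adjusted p = 0.187 with an estimated correlation. Cytokines and chemokines fell for 4 of 24 with 20 not passing (5 lower adjusted over the list alone; median -0.22, camera adjusted p 0.000105, but adjusted p = 0.732 with an estimated correlation). Beside Cxcl5 and Ccl2, Cxcl10 was at -1.20 (adjusted p 0.148) and Ccl12 at -0.57 (adjusted p 0.0751). NF-kappaB feedback and adhesion targets fell for 2 of 20 with 18 not passing (7 lower adjusted over the list alone; camera adjusted p 4.44e-06, but adjusted p = 0.732 with an estimated correlation). Gadd45b fell by 0.36, while Ier3 was at -0.45 (adjusted p 0.0626) and Tnip3 at -0.42 (adjusted p 0.0879). Platelet markers had none of 11 passing (1 higher adjusted over the list alone), with a camera adjusted p of 0.000857 but an adjusted p = 0.732 with an estimated correlation. Ppbp was at 0.38 (adjusted p 0.177) and Tubb1 at 0.31 (adjusted p 0.228). Cardiac muscle markers likewise had none of 16 passing, also adjusted over the list alone, with a camera adjusted p of 0.0011 but an adjusted p = 0.754 with an estimated correlation. Ttn was at 0.43 (adjusted p 0.295) and Nppa at 0.34 (adjusted p 0.603).

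Immediate-early transcription factors and phosphatases fell for 3 of 27 with 24 not passing (1 higher and 6 lower adjusted over the list alone). Egr2 fell by 0.56, Fosl1 by 0.42 and Myc by 0.41, and Fosb was at -0.71 (adjusted p 0.0573). The immediate-early call (camera adjusted p 0.043, but adjusted p = 0.82 with an estimated correlation) was lost without high stretch normocapnia replicate 1, 3, 5 or 7 or high stretch hypercapnia replicate 1, 2, 6, 7 or 9, with adjusted p from 0.0577 to 0.14. NRF2, metallothionein and antioxidant genes fell for 4 of 22 with 18 not passing (7 lower adjusted over the list alone). Osgin1 fell by 0.43 beside Hmox1, and Slc7a11 was at -0.47 (adjusted p 0.246). The call of the NRF2 list (camera adjusted p 0.0219, but adjusted p = 0.732 with an estimated correlation) was lost without high stretch hypercapnia replicate 2 (adjusted p 0.0561). Matrix metalloproteinases and their inhibitors fell for 2 of 21 with 19 not passing (3 lower adjusted over the list alone), with the tenascin gene Tnc lower by 0.61 beside Timp1. The call of the matrix list (camera adjusted p 0.03, but adjusted p = 0.732 with an estimated correlation) was lost without high stretch normocapnia replicate 1 or 6 or high stretch hypercapnia replicate 2, 3 or 6, with adjusted p from 0.0501 to 0.0751. Of 17 circadian clock genes 1 passed and 16 did not (3 higher adjusted over the list alone), with Dbp at 0.50 (adjusted p 0.399). The repressor gene Cry2 was at 0.36, a call lost without the lowest-spread array of each group (0.29, adjusted p 0.0642). The clock list's call (camera adjusted p 0.043, but adjusted p = 0.754 with an estimated correlation) was lost without high stretch normocapnia replicate 2, 3, 4 or 6 or high stretch hypercapnia replicate 2, 3, 4, 6, 7 or 8, with adjusted p from 0.0533 to 0.103. Among genes above the median level the call was also lost for the inflammatory cytokines and chemokines (adjusted p 0.0831), the NRF2, metallothionein and antioxidant genes (0.0676), the matrix metalloproteinases and their inhibitors (0.315), the immediate-early transcription factors and phosphatases (0.17), the circadian clock (0.174), the platelet markers (0.0512) and the cardiac muscle markers (0.0657).

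Limma called 1109 genes for hypercapnia at high stretch, 497 higher and 612 lower, none by 1 log2 unit or more, and with each array centred on its median 354 higher and 721 lower. With array weights the count was 2052. Camera called 10 lists, 0 with an estimated correlation (17 had an unadjusted p under 0.05 with the preset correlation, and fry called 1). The number of lists was 5 without high stretch hypercapnia replicate 2 and 20 without replicate 10. The calls of 5 named genes were lost in fits with 1 array less. Spic lost it without high stretch normocapnia replicate 5 (-0.73, adjusted p 0.0514), and Myc without high stretch normocapnia replicate 1, 3, 5 or 7 or high stretch hypercapnia replicate 2 (adjusted p 0.0521 to 0.0599). Osgin1 lost it without the same 5 arrays or high stretch hypercapnia replicate 1 (adjusted p 0.0509 to 0.0623). Rdh12 lost it without high stretch normocapnia replicate 1, 2, 3 or 10 or high stretch hypercapnia replicate 2, 4, 8, 9 or 10 (adjusted p 0.0579 to 0.0709). Stat4 lost it without high stretch normocapnia replicate 1, 2, 3, 5, 7 or 9 or high stretch hypercapnia replicate 2, 4, 8 or 10 (adjusted p 0.0527 to 0.0751).

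Whether CO2 moved the same genes at both stretch levels was tested across the 1114 genes called in either comparison, which share no arrays. Pmvk, Ramp3, Tubb2b, Erf, Capn5, Fbxo44 and Zbtb7b were higher in both, 7 of the 8 genes that rose at low stretch against 0.199 expected for independent lists. Of the 15 genes that fell at low stretch 11 also fell at high stretch against 0.46 expected, among them Ints7, Fastkd2, Nmnat1, Mlst8, Ino80c, Fancl, Ubxn8 and Slc9a8. Both contrasts used 1 fit with a shared variance per gene. The lists are therefore not fully independent, and the expected numbers may be too low. The changes at both levels had the same sign for 90.3% of the 1114 genes, with Pearson's r of 0.779 and Spearman's rho of 0.752 across genes, which are not independent replicates. Permuting the CO2 labels within each stretch level 100 times gave r from -0.668 to 0.716, for a two-sided permutation p of 0.0099, the smallest these permutations can give. The permuted same-sign share ran from 14.9% to 86.4%. The 1114 genes were those called with the real labels and were not called again in each permutation. The permuted r is therefore not selected as the observed r is, and this p does not allow for that selection. Over all 19938 genes, with no such selection, r was 0.394 (permutation p 0.0495) and the same-sign share was 60.5%.

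**Figure D3:**
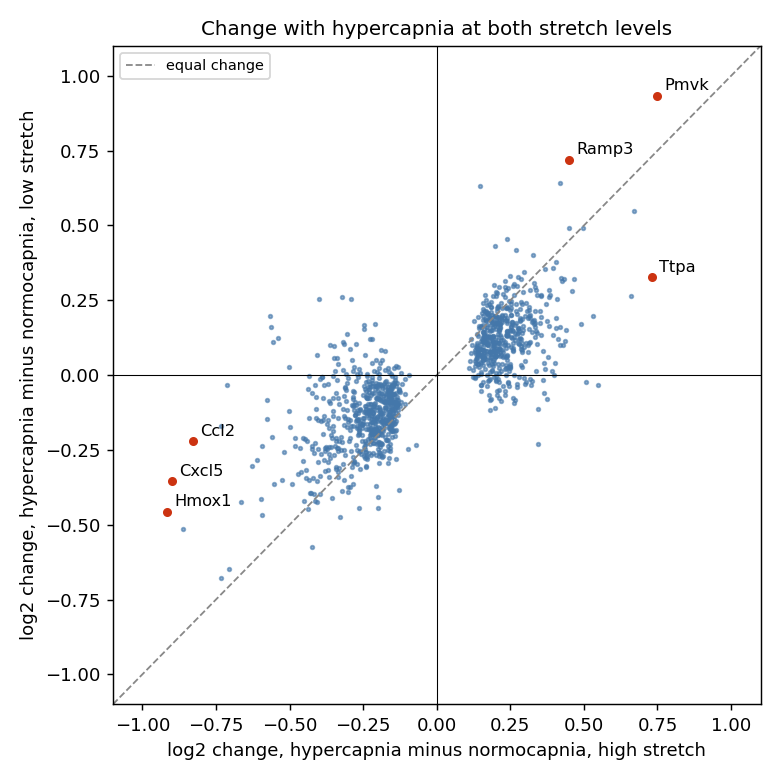
Log2 change with hypercapnia at high stretch (horizontal, 10 arrays against 10) and at low stretch (vertical, 5 against 5) for the 1114 genes called in either comparison, 1 point per gene, with a dashed line of equal change. Pmvk lay at 0.75 and 0.93, Ttpa at 0.73 and 0.33, and Hmox1 at -0.92 and -0.46. Of the points 90.3% had the same sign on both axes, against 60.5% over all genes tested.

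Whether hypercapnia moved the genes that high stretch had changed back towards low stretch was tested with separate subsets of 5 high stretch normocapnia arrays in each contrast, since both contrasts hold that group. Ttpa was lower at high stretch and higher with CO2, and Il6, Ccl2, Hmox1 and Timp1 were higher at high stretch. These single-gene changes used all high stretch normocapnia arrays in both contrasts, so chance values in that group alone could give a reversal. Ttpa, Ccl2, Hmox1 and Timp1 were also among the largest changes with CO2, so no return towards low stretch can be read from them. With CO2, Ccl2, Hmox1 and Timp1 fell, while Il6 was at 7.70 ± 0.66 without and 7.36 ± 0.49 with CO2 (SD, n = 10 each). Pmvk moved the other way, rising with high stretch by 0.97 (adjusted p 4.95e-05) and further with CO2 by 0.75, and Ttpa had been chosen on these arrays. Over 100 random splits a mean of 72.3% (SD over splits 3.8) of the stretch genes changed in the opposite direction with CO2, 71.4% of those that rose and 73.6% of those that fell with stretch. Permuting the CO2 labels among the 20 high stretch arrays gave shares from 12.7% to 85.5% with a median of 49.1%. This gave a two-sided permutation p of 0.188, so the observed share was not beyond chance. Each permuted share came from a single split and the observed share is a mean over splits, which may widen the permuted range. Among stretch changes of at least 1 log2 unit the share was 87% (permutation p 0.099). Without the split it was 77.1% (permutation p 0.356).

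High stretch was also compared with low stretch in hypercapnia. Il6 rose 6.57-fold from 4.64 ± 0.34 (SD, n = 5) to 7.36 ± 0.49 (SD, n = 10, adjusted p 1.06e-09), Cldn4 4.22-fold, Ptgs2 4.18-fold, Atf3 4.07-fold and Sfn 3.01-fold. All 10 high stretch arrays lay above every low stretch array in these 5 genes. Slc10a5 fell 1.98-fold, Ankub1 1.83-fold, Fam216b 1.81-fold, Rassf9 1.81-fold and the homeobox gene Meox2 1.76-fold. Immediate-early transcription factors and phosphatases rose for 20 of 27 genes with 7 not passing (23 higher adjusted over the list alone; camera adjusted p 1.59e-26, and adjusted p = 0.0088 with an estimated correlation). Egr2 rose 2.95-fold, Nr4a1 2.83-fold and Fosb 2.56-fold. Inflammatory cytokines and chemokines rose for 11 of 24 with 13 not passing, also adjusted over the list alone (camera adjusted p 5.55e-11, and adjusted p = 0.0456 with an estimated correlation). Ccl3 rose 2.88-fold and the alarmin gene Il33 1.9-fold. Of the stretch-responsive targets 11 of 22 rose, 1 fell and 10 did not pass (12 and 1 adjusted over the list alone; camera adjusted p 8.87e-10, and adjusted p = 0.00612 with an estimated correlation). Ccn1 rose 2.37-fold and F3 2.08-fold. Hypoxia-inducible and glycolytic genes rose for 7 of 25 with 18 not passing (7 higher and 1 lower adjusted over the list alone; camera adjusted p 0.000101, and adjusted p = 0.0374 with an estimated correlation). Bhlhe40 rose by 0.97 and Adm by 0.74. Ttpa (-0.35, adjusted p 0.0966), Adam17 (0.01, adjusted p 0.95) and Alox5 (0.08, adjusted p 0.619) did not pass. Limma called 2017 genes, 1082 higher and 935 lower, and camera 19 lists, 7 of them with an estimated correlation. Without low stretch hypercapnia replicate 5 the gene count was 1278. The stretch contrasts in normocapnia and hypercapnia, which share no arrays, had 927 higher genes in common against 94.4 expected for independent lists and 644 lower genes against 89.4. These contrasts also shared a variance per gene in the fit, so the expected numbers may be too low.

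The interaction, the change with CO2 at high stretch minus that at low stretch, was the test of whether the CO2 response depended on stretch. No gene passed in limma, with 893 genes at an unadjusted p under 0.05 against 997 expected by chance. The genes with the smallest unadjusted p were Krtap17-1 (-0.67 ± 0.15, SE, adjusted p 0.841), Ubl7 (0.26, adjusted p 0.841), Slc22a19 (-0.44, adjusted p 0.997), Plac1 (-0.58, adjusted p 0.997) and Gdnf (-0.47, adjusted p 0.997). Ttpa (0.40 ± 0.19, SE), Adam17 (0.03) and Alox5 (-0.09) each had an adjusted p of 0.997. In the cardiac muscle list (median 0.31) Nppa was at 0.75 and Ttn at 0.53, and in the platelet list (median 0.25) Tubb1 was at 0.57 and Ppbp at 0.55. In the immediate-early list (median -0.18) Fosb was at -0.79, Egr2 at -0.72 and Egr1 at -0.63. No member of these 3 lists passed, over all genes or adjusted over the list alone. Camera called 9 lists, 0 of them with an estimated correlation (12 had an unadjusted p under 0.05 with the preset correlation, and fry called 0), and 14 without low stretch normocapnia replicate 1.

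**Figure D4:**
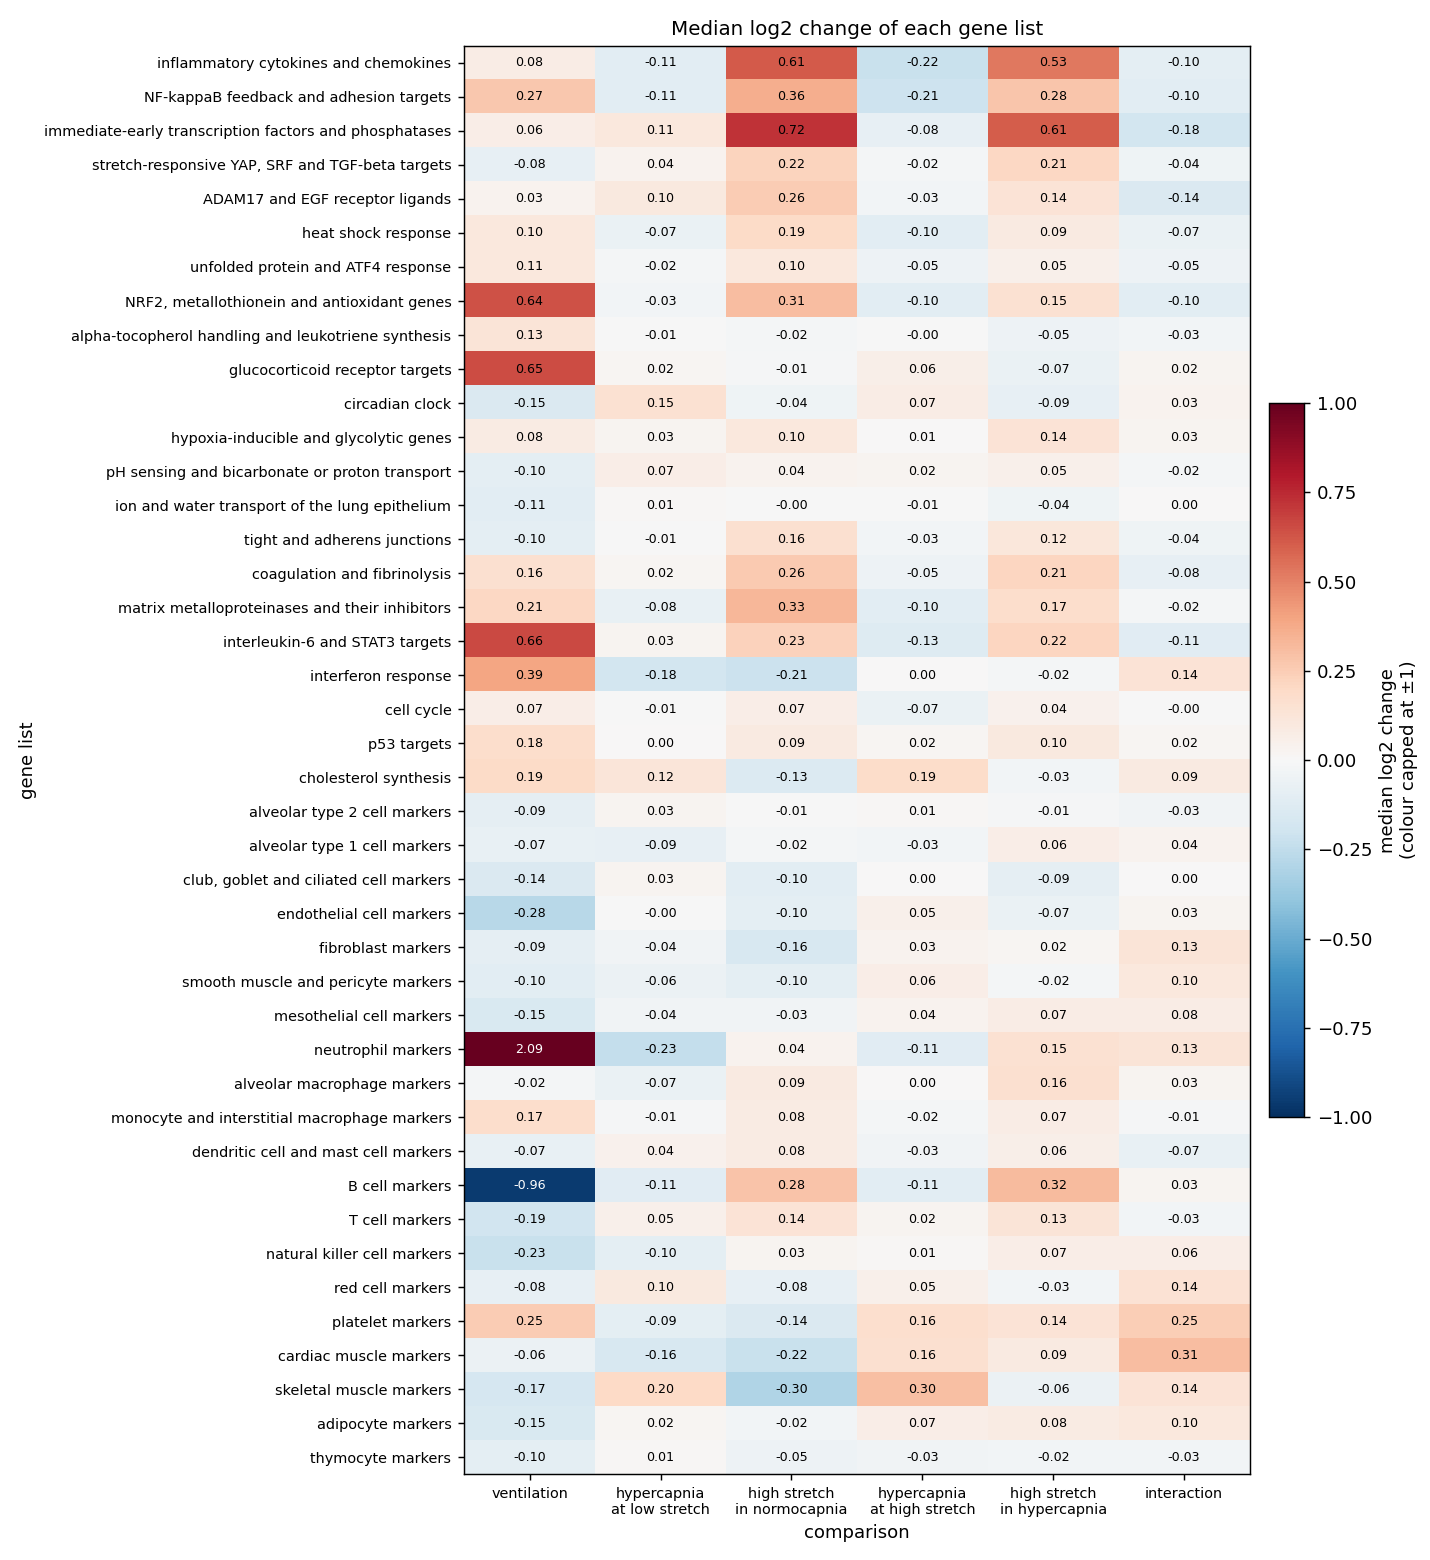
Median log2 change of the measured members of each of the 42 gene lists (vertical) in each of the 6 comparisons (horizontal), printed in each cell and shown by colour, which is capped at an absolute value of 1. Neutrophil markers stood at 2.09 and B cell markers at -0.96 for ventilation, and immediate-early genes at 0.72 for high stretch in normocapnia.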

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

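The weighing of array spread, of resident cell share and of group size was chosen after the results were seen, while the splits of arrays were planned. Arrays stood out where 1 array lay far from the others of its group by Dixon's ratio, the gap to the nearest array over the range of the group. This held for 30 of 471 groups tested (6.37%), and chance gives about 1 in 20.

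Among non-ventilated arrays, replicate 1 was highest for Cd79a (0.816), Cr2 (0.74), Lrg1 (0.718) and the B cell markers (0.786), replicate 4 lowest for Hmox1 (0.805) and replicate 5 highest for F13a1 (0.871). In low stretch normocapnia replicate 1 was highest for Atf3 (0.783) and Egr1 (0.78), replicate 4 lowest for Slc9a8 (0.731) and highest for Tubb1 (0.824), and replicate 5 lowest for Fam216b (0.942) and highest for Ccr7 (0.749), Ttn (0.789) and the T cell markers (0.773). In low stretch hypercapnia replicate 1 was highest for Plac1 (0.718), Ccl3 (0.775), the neutrophil markers (0.778) and the inflammatory cytokines and chemokines (0.814).

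In high stretch normocapnia replicate 6 was highest for Adam17 (0.59) and replicate 1 for Adamts4 (0.625), and replicate 9 was lowest for Sele (0.537). In high stretch hypercapnia replicate 1 was highest for Slc22a19 (0.511), replicate 3 for Ptgs2 (0.509), replicate 5 for Cxcl5 (0.499) and replicate 8 for Pmvk (0.505), and replicate 2 was lowest for Sfn (0.483). Replicate 10 of that group was highest for Cxcl10 (0.815, at 11.76 against 8.25 for the nearest array), Ccl2 (0.501), the inflammatory cytokines and chemokines (0.478) and the NF-kappaB targets (0.474).

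The CO2 response differed between stretch levels for 9 lists by camera, with these adjusted p: cardiac muscle 5.49e-08, platelet 1.88e-06, immediate-early 5.94e-05, ADAM17 and EGF receptor ligands 0.000962, fibroblast 0.011, smooth muscle and pericyte 0.0265, and cytokines, interferon response and cholesterol synthesis 0.0364 each. With an estimated correlation the adjusted p were 0.626 for cardiac muscle, platelet and ADAM17 and EGF receptor ligands, 0.757 for immediate-early, fibroblast and smooth muscle, and 0.909 for the other 3. Of 100 splits of the arrays 74 gave as many lists, up to 27, so chance could not be excluded. For genes 100 of 100 gave at least the 0 called, up to 2, which holds by definition and tests nothing.

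For 4 other comparisons the number of genes called was reached only by the real split of 100: 2353 for ventilation (1 split, highest other 1078), 3646 for high stretch in normocapnia (1, highest other 1112), 1109 for hypercapnia at high stretch (1, highest other 4) and 2017 for high stretch in hypercapnia (1, highest other 821). Chance was thus argued against for these 4 counts, as far as 100 splits can show. The 23 genes for hypercapnia at low stretch were also reached only by the real split (1 of 100, highest other 12). That count was 3 to 7 in 6 fits without 1 array and 0 with only the compared groups, so chance was argued against for the planned fit only. For lists chance was argued against for ventilation alone (26 lists, reached by 2 of 100 splits with the real one included, highest other 28), and not excluded. Chance could account for the number of lists for hypercapnia at low stretch (5 lists, 97 of 100 splits, highest other 22), high stretch in normocapnia (17, 32 of 100, highest other 25), hypercapnia at high stretch (10, 66 of 100, highest other 21) and high stretch in hypercapnia (19, 20 of 100, highest other 24).

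With ventilation neutrophil markers rose while B cell and endothelial markers fell, and incoming neutrophils could lower the share of all resident cells. Relative to alveolar type 2 markers the change was -0.81 for B cell markers (SE 0.126, exact p 0.00794). It was -0.22 for endothelial markers (SE 0.0396, exact p 0.00794), in both cases the smallest two-sided p of 252 splits. This argues against a lower resident share alone, as far as the type 2 list tracks that share. That list held Lyz2 and Chil1, which are not confined to these cells, and lay higher in signal (mean 12.2 without ventilation). Fibroblast markers, nearer in level, went from 10.49 ± 0.03 to 10.36 ± 0.08 (SD, n = 5 each). Endothelial markers went from 10.61 ± 0.04 to 10.26 ± 0.06 (SD, n = 5 each). Array spread as a covariate gave 2.04 (SE 0.268) for neutrophil, -0.94 (SE 0.0992) for B cell and -0.35 (SE 0.0459) for endothelial markers, but the mean spread was 2.22 in both groups, so that fit could not move these changes and decides nothing. Loss of cells and lower expression within cells both remain open.

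Genes changed by high stretch tended to move the opposite way with CO2, which could come from the normocapnia arrays in both contrasts or from array spread. With these arrays split between the contrasts the share was 72.3% (permutation p 0.188, permuted median 49.1%). No array was then in both contrasts, which argues against shared arrays as the source of that share. With the spread removed as well it was 71.6% (permutation p 0.188, permuted shares 14.2 to 85.9%). The mean spread was 2.24 in both high stretch groups, so that fit could hardly move the change with CO2 and decides nothing. The share itself was not beyond chance, so no effect of CO2 can be read from it.

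More genes were called for hypercapnia at high stretch (1109) than at low stretch (23), which could come from the larger groups. With 5 against 5 high stretch arrays a median of 127 genes was called (0 to 665 over 100 draws), and 9 draws gave 23 or fewer, so group size may account for the difference. A larger effect at high stretch was also compatible with the data. The ratio of the low stretch change to the held-out high stretch change was 0.67, in genes selected at high stretch. Its jackknife SE was 0.149, and it ran from 0.568 to 0.736 with 1 low stretch array left out. High stretch arrays were not left out, so this SE and range do not hold their part of the uncertainty. Both remain open, and no gene passed for the interaction.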

How the results depend on the processing

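No result that passed changed direction under any alternative, and the cause of the changes given here was not tested except where fewer arrays or genes were used. With only the compared groups 1385 genes were called for ventilation, and 0 genes and 3 lists for hypercapnia at low stretch. Genes above the median level gave 78 genes and 1 list for hypercapnia at low stretch, and 2, 11 and 4 lists for hypercapnia at high stretch, high stretch in hypercapnia and the interaction. For hypercapnia at low stretch, centring gave 3 lists, a second quantile normalization 64 genes and 3 lists, the mean of probe sets 3 lists, all probe sets 4 genes, and the spread covariate, chosen after the data were seen, 100 genes and 3 lists (6 lists for hypercapnia at high stretch). Array weights gave 2052 genes for hypercapnia at high stretch. An estimated correlation left 6 lists for ventilation, 0 for hypercapnia at low stretch, 4 for high stretch in normocapnia, 0 for hypercapnia at high stretch, 7 for high stretch in hypercapnia and 0 for the interaction; fry gave 0, 1 and 0 for hypercapnia at low and at high stretch and the interaction.

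Without 1 array, hypercapnia at low stretch had 3 to 28 genes and 3 to 9 lists, high stretch in hypercapnia 1278 to 2191 genes, hypercapnia at high stretch 5 to 20 lists and the interaction 7 to 14 lists. The ranges were 1749 to 2405 genes for ventilation, 2581 to 3768 for high stretch in normocapnia, 855 to 1176 for hypercapnia at high stretch, 69.4 to 75.6% for the opposed share and 0.725 to 0.802 for the correlation of CO2 effects. Of the named genes 2060 values were the same, 35 lost and 20 gained a call and 9 moved under the other settings, and of the lists 459 kept and 69 lost their call. Without 1 array 3161 gene values were the same, 135 lost and 15 gained a call and 9 moved, and 642 lists kept and 33 lost theirs. Signal over background could not be measured from the deposited values, so what it limits is not known.

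The replicate numbers were not taken to pair the arrays, because in no comparison did every pair correlate above 0.1. This rule does not exclude a structure shared by arrays of the same number. For high stretch in normocapnia 4 of 5 arrays correlated best with their own number, and the count was 3646 without the block. Such a structure therefore remains open. As a block they gave 1269 genes for high stretch in hypercapnia, and 2361, 16, 2626 and 1128 for ventilation, hypercapnia at low stretch, high stretch in normocapnia and hypercapnia at high stretch. With the block, Dynlrb2 was at -0.22 (adjusted p 0.122) for high stretch in normocapnia, and the club, goblet and ciliated cell markers lost their call there. Arrays of the same number correlated above 0.1 in 3 of 5, 1 of 5, 4 of 5, 4 of 10 and 2 of 5 pairs of ventilation, hypercapnia at low stretch, high stretch in normocapnia, hypercapnia at high stretch and high stretch in hypercapnia, and 2, 0, 4, 1 and 1 arrays correlated best with their own number.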

Other observations

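The ribosome biogenesis test was chosen after the high stretch result was seen. Some members of the fixed lists not named in the report for these comparisons moved with ventilation or stretch. Alox5ap, which encodes the activating protein of 5-lipoxygenase, rose 2.04-fold with ventilation (adjusted p 6.07e-05), and Birc3, an inhibitor of apoptosis, 1.73-fold (adjusted p 8.95e-05). With high stretch in hypercapnia the kinase gene Plk2 rose 2.82-fold (adjusted p 2.87e-11), and Foxj1, a regulator of cilia, fell by 0.41 (adjusted p 8.8e-06).

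Ribosome biogenesis genes were noticed among those lower with hypercapnia at high stretch, where 28 of 39 measured passed as lower and the median was -0.26; Nop2 was at -0.33, Utp20 at -0.41, Rrp12 at -0.42 and Pes1 at -0.25. The hypothesis that these genes are lower at low stretch too was tested on the other arrays. There the median was -0.16, with 34 of 39 lower and none passing, Nop2 at -0.21, Utp20 at -0.42, Rrp12 at -0.24 and Pes1 at -0.16. Of all genes called lower with hypercapnia at high stretch, 91.3% were also lower at low stretch. The number of lower genes is therefore not particular to this list. Camera gave p = 1.45e-15 with the preset correlation, but p = 0.0561 with an estimated correlation of 0.561, and fry gave p = 0.0274. The hypothesis stays open.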
